A study of Arabidopsis thaliana with 12 samples.

How the data were processed

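Total RNA of 12 samples of Arabidopsis root explants was sequenced as stranded, ribosomal RNA-depleted libraries with paired reads of 125 nt. Per the submitters' processing notes, reads were made with bcl2fastq 2.17.1.14, aligned with TopHat2 2.0.14 to TAIR10 and compared with Cuffdiff 2.2.1.3, with no options stated. The authors' deposited table gives expression in FPKM for each group, with a p-value and a q-value (an adjusted p-value) for each of the 6 pairwise comparisons of the 4 groups, per the file headers. It holds 33557 features, and the 3 replicates of a group are not shown separately. The deposited q-value was found to equal a Benjamini-Hochberg adjustment over all 115069 tests in the table (largest difference 5.3e-07). A further 86270 entries were not tested by the authors and 3 carried a high-data status. The smallest p-value in the authors' deposited table was 5e-05. For 32809 features (97.8%) a gene of the same identifier was found in the reference annotation, from which strand and gene class were taken. Depth per library was not known, so the precision of a value was judged from the standard error that its test implies. The median such standard error of a log2 fold was 0.129 and 0.131 for the cytokinin effects in wild type and in the groups labelled CPL4RNAi, and 0.134 and 0.136 for the genotype differences without and with cytokinin. The median distance from a fold that was not called to its 95% bounds was 0.25, 0.25, 0.26 and 0.27.

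Of the pairwise comparisons 4 were reported, and the other pairs served to recover variances. Log2 folds were computed from the group FPKM without a pseudocount, and a gene was called at a deposited q-value at or under 0.05. The standard error of a fold was taken as its size over the normal quantile of the deposited p-value. It reflects the variance that Cuffdiff modelled and not an observed spread of replicates. A p-value at the floor gives a quantile of 4.06 or more, so the standard error is then at most 0.247 of the fold. The difference of the cytokinin effect between genotypes needs the summed variance of all 4 groups. This was solved from pairs of comparisons that together hold the 4 groups, using p-values at or under 0.95, and a gene was left out where its pairs differed by more than 10.0% (476 genes). The planned test used the deposited test statistic, and the p-value took its place because the table has no such column. Where no pair could be solved, the largest standard error that the floor allows was used, a choice made after the data were seen. Of 18514 genes tested for the difference, 17040 had a solved standard error and 1474 an upper bound. Across 13014 genes with several pairs the median spread of the standard error was 1.14%. Tested on simulated data, the procedure recovered 54.0% of log2 differences of 1 and 87.0% of log2 differences of 2, and 4 of its 145 calls (2.76%) had no simulated change. The simulation covered 17516 genes with at least 1 solvable pair, and assumed normal errors and equal variance in the 4 groups. Genes with only an upper bound, which gave 229 of the 460 calls reported below, were not simulated. The 2.76% is therefore no error rate of those calls.

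The comparisons, 21 gene lists with 333 genes and the rule for named genes were fixed before the data were examined. Named were the CPL genes, the type-A response regulators, WUS, CLV3, STM, CUC1, CUC2, ESR1 and ESR2 whatever their values. Added for each comparison were the 6 genes called higher and the 6 called lower with the largest fold among those with an FPKM of 5 or more in the higher group and above 0 in the lower. From each list the 2 called members with the largest fold were added, and for the difference the 5 largest in each direction with an FPKM of 5 or more in a group. Named genes without a well-known symbol, and some list members, were left out of the text for length, and 1 named list member is not reported here. Each list was tested per direction against all other tested genes with a 2-sided Fisher's exact test, adjusted by Benjamini-Hochberg over 168 tests. Counts adjusted over the list alone used Benjamini-Hochberg on the deposited p-values of its members. Overlaps of calls were compared with independent lists by Fisher's exact test. Covariances of folds between comparisons that share a group were set against 100 simulated sets of unchanged groups with equal variance. So was that of the averaged genotype and cytokinin effects. Genes downstream of small nuclear RNA genes were taken within 2000 bases on the same strand.

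Alternatives covered the q threshold (0.01), a 2-fold minimum, a pseudocount of 1, an FPKM minimum of 1, adjustment within a comparison, protein-coding nuclear genes alone (this and the FPKM minimum with adjustment within the genes left), recentring on genes with an FPKM of 5 or more, the background of the list tests and the distance of 1000 or 5000 bases. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.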

Results

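RNA was sequenced from cultured Arabidopsis root explants, to ask how a construct labelled CPL4RNAi and a low dose of cytokinin change transcript levels while shoots are being induced from roots. CPL4 is a phosphatase that acts on the tail of the largest subunit of RNA polymerase II. Explants were wild type (Col-0 gl1) or of a line that the sample titles call CPL4RNAi, while the genotype field of the same samples reads CPL4 KO. Shoots were cut from 10-day seedlings, and the root segments spent 5 days on callus-inducing medium, which is rich in auxin. They were then kept for 72 hours on a shoot-inducing medium with 0.05 mg/L of the cytokinin isopentenyladenine or with 0 mg/L, and were 18 days old at harvest. The 12 samples form 4 groups of 3. The series calls the replicates biological without saying whether they were separate cultures, and the authors' tests rest on a variance that was modelled from them. The values analysed here are the authors' group FPKM for 33557 annotated features, with no values per replicate. The depth of each library is unknown from the values used here. Of the features, between 18155 and 18486 had an FPKM of 1 or more in a group. A gene was called where the q-value in the authors' deposited table was at or under 0.05. The standard errors given below are those that the deposited p-values imply, and where a p stands at its floor only the largest possible standard error is given.

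The targeted gene was examined first, as a check of the labels. CPL4 (AT5G58003; chromosome 5, 23479804 to 23482048, TAIR10, a protein-coding gene) had an FPKM of 14.5 in wild type without cytokinin and 13.9 with it. In the groups labelled CPL4RNAi it had 36.3 and 32.2. CPL4 was therefore higher, not lower, in the groups labelled CPL4RNAi, by 1.33 on the log2 scale without cytokinin (SE at most 0.33) and by 1.21 with it (SE at most 0.30). Its q was 2.7e-04 in each medium in the authors' deposited table, the smallest q that table holds. Because the gene goes against the label, each direction drawn between genotypes below is that of the groups as labelled. The related phosphatase gene CPL3 (AT2G33540) also rose, by 0.59 and 0.64. CPL1 (AT4G21670) and CPL2 (AT5G01270) rose with cytokinin present, by 0.44 and 0.29, whereas without it their differences of 0.30 and 0.19 were not called. All 4 members of the CPL family were thus called higher with cytokinin (4 adjusted over the list alone), and 2 without it (2 adjusted over the list alone). None of the 4 was called for the cytokinin effect in either genotype.

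In wild type, cytokinin raised type-A response regulators, cytokinin inactivation genes and xylem genes, and lowered genes of the root epidermis, endodermis and cap. The type-A response regulators are early cytokinin targets that feed back on the signal, and 8 of 9 tested rose (9 adjusted over the list alone; Fisher's exact test, adjusted exact p = 2.5e-07). ARR7 (AT1G19050) went from 9.54 to 33.5 FPKM, a log2 change of 1.81 (SE at most 0.45). ARR3, ARR6, ARR5 and ARR4 rose by 1.41, 1.00, 0.95 and 0.79, and ARR8 and ARR9 by 0.38 and 0.37. ARR16 went from a listed 0 to 0.882 FPKM and was called. ARR15 went from 0.168 to 3.91 FPKM, a log2 difference of 4.54 with an SE of 2.29 that was not called, and ARR17 was not tested. Of 10 genes for cytokinin inactivation, 6 rose (8 adjusted over the list alone; adjusted exact p = 2.5e-04). They included the cytokinin oxidase genes CKX4 and CKX1, which rose by 4.99 (SE at most 1.23) and 2.07 (SE at most 0.51). Cytokinin synthesis and perception genes had 4 of 17 tested members lower and 1 higher (the same counts adjusted over the list alone; adjusted exact p = 0.015 for lower). AHP6, an inhibitor of cytokinin signalling in the root vasculature, fell by 1.69, and CYP735A2, a cytokinin hydroxylase, rose by 1.23.

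The xylem and secondary wall list, which holds a xylem master regulator, the xylem cysteine peptidases and the cellulose synthases of the secondary wall, had 5 of 6 members higher in wild type with cytokinin (6 adjusted over the list alone; adjusted exact p = 1.6e-04). XCP2 (AT1G20850) went from 1.82 to 13.5 FPKM, a rise of 2.89 (SE at most 0.71). CESA4 rose by 2.77 (SE 1.05). Outside the list, the cambium markers PXY, WOX4 and ATHB8 went from 10.7 to 29.3, from 4.26 to 13.0 and from 26.7 to 43.4 FPKM. The phloem markers SUC2, APL and SEOR1 changed less, from 23.7 to 33.6, from 6.11 to 6.41 and from 5.57 to 6.54 FPKM. In the list of root epidermis, endodermis and cap genes 5 of 9 fell (5 adjusted over the list alone, beside 1 higher; adjusted exact p = 1.6e-04). Among them was the Casparian strip gene CASP1, which fell by 2.27. Root meristem and callus regulators had 4 of 15 members lower and 2 higher (5 and 2 adjusted over the list alone; adjusted exact p = 0.0097 for lower). The callus regulator LBD29 fell by 1.18 and the root stem cell gene PLT2 by 0.44. All 3 tested members of the stomatal lineage and shoot epidermis list fell (3 adjusted over the list alone; adjusted exact p = 6.6e-04), ATML1 by 0.48 and PDF2 by 0.44. The 3 are shoot epidermis genes, and no stomatal lineage member of the list was tested. Early auxin response genes had 5 of 13 members higher and 1 lower (the same counts adjusted over the list alone; adjusted exact p = 0.0056 for higher). IAA3 rose by 1.17 and IAA14 fell by 0.78. Of 7 heat shock genes 4 rose (4 adjusted over the list alone; adjusted exact p = 0.0035), with MBF1C at 0.84 and HSP90.1 at 0.61.

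Among the shoot regeneration genes in wild type, ESR1, a transcription factor that promotes shoot regeneration, rose from 0.397 to 1.39 FPKM, by 1.80 (SE 0.59), and RAP2.6L rose by 0.43. CUC1 and CUC2 differed by -0.07 (SE 0.30) and 0.13 (SE 0.14), which was not called. WUS was listed at 0 with and without cytokinin, and STM and CLV3 stood under 0.1 FPKM, so that none of these was tested. Among called genes with an FPKM of 5 or more in the higher group, AT5G47980 rose most, by 5.19 (SE 1.33), followed by VSP1, a vegetative storage protein gene that jasmonate induces, by 4.47. CYP705A5, a neighbour of AT5G47980 in the gene cluster for the triterpene thalianol, rose by 4.01 (SE at most 0.99), and the sulfotransferase gene ST4B by 3.89. In the same set the largest falls were in AT3G01190, AT2G45180 and GSTF14, at -5.29, -4.00 and -3.88. Called members of lists that did not pass the enrichment test included the auxin genes TAA1 and PIN2, which fell by 1.21 and 0.99, the cyclin gene CYCD3;1, which rose by 0.40, and the flavonoid gene CHS, which rose by 1.06. For the cytokinin effect in wild type 18827 genes were tested in total, and 1938 were called, 1239 higher and 699 lower. At least a 2-fold change was seen in 518 of them. With adjustment within this comparison alone, 1320 genes were called. At a q of 0.01, the adjusted p became 0.21 for the root meristem and callus regulators and 0.079 for early auxin response, which ended both calls.

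In the groups labelled CPL4RNAi the type-A response regulators also rose with cytokinin, while xylem genes fell and salicylic acid genes rose. Of 8 tested type-A response regulators 7 rose (7 adjusted over the list alone; adjusted exact p = 7.4e-06). ARR7 went from 6.35 to 46.7 FPKM, by 2.88 (SE at most 0.71), ARR3 went from 2.92 to 12.5 FPKM, and ARR6, ARR4 and ARR5 rose by 1.57, 1.36 and 1.28. Of the genes for cytokinin inactivation 6 of 10 rose (6 adjusted over the list alone; adjusted exact p = 6.6e-04), with CKX1 at 2.83 and CKX5 at 1.76. Cytokinin synthesis and perception genes had 7 of 17 members lower and 4 higher (8 and 5 adjusted over the list alone; adjusted exact p = 0.0025 for lower). The cytokinin-activating genes LOG1 and LOG4 fell by 1.45 and 1.23. All 6 xylem and secondary wall genes fell (6 adjusted over the list alone; adjusted exact p = 1.4e-05), CESA8 by 0.83 and CESA4 by 0.80. Of 9 tested salicylic acid and immune response genes 8 rose (8 adjusted over the list alone; adjusted exact p = 1.2e-06). EDS5 and EDS1, which act in salicylic acid export and in immune signalling, rose by 1.08 and 1.06.

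Root meristem and callus regulators had 7 of 15 members lower and 2 higher in the groups labelled CPL4RNAi (the same counts adjusted over the list alone; adjusted exact p = 0.0012 for lower). LBD29 fell by 2.35 (SE 0.60) and PLT5 rose by 0.82. Of 11 root epidermis, endodermis and cap genes 5 fell (5 adjusted over the list alone; adjusted exact p = 0.0087), CASP1 by 1.88. In the list of auxin synthesis and transport genes 7 of 14 fell and 1 rose (7 and 2 adjusted over the list alone; adjusted exact p = 8.8e-04 for lower). The auxin efflux carrier gene PIN2 fell by 0.76, and YUC4, for an auxin synthesis enzyme, rose by 0.84. Early auxin response genes had 6 of 13 members higher and 1 lower (7 and 1 adjusted over the list alone; adjusted exact p = 0.0025 for higher), with IAA5 and IAA3 at 2.23 and 1.54. Glutathione S-transferases, detoxification enzymes encoded in part by tandem copies that can share reads, had 10 of 29 members higher and 3 lower (10 and 4 adjusted over the list alone; adjusted exact p = 8.7e-04 for higher). GSTU6 rose by 0.93 and GSTU9 fell by 1.36.

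ESR1 rose from 0.769 to 4.54 FPKM with cytokinin in the groups labelled CPL4RNAi, by 2.56 (SE at most 0.63). CUC1 rose by 0.45 (SE 0.14), and CLV1, a receptor gene of the shoot meristem, fell by 0.86. WUS and STM differed by -0.04 (SE 0.31) and 0.01 (SE 0.12), which was not called. Among called genes with an FPKM of 5 or more in the higher group, the largest rises were VSP1 at 7.27 (SE 3.00), AT2G16005 at 4.67, AT5G47980 at 4.52 and PERK4 at 4.43. The largest falls of that set were AT3G01190 at -4.90, SBP3, a selenium-binding protein gene, and AT2G45180 at -3.19. In total 19156 genes were tested and 3313 called, 1612 higher and 1701 lower, with 669 changed at least 2-fold. With adjustment within this comparison alone, 2561 genes were called. At a q of 0.01, the adjusted p became 0.070 for cytokinin synthesis and perception, 0.19 for auxin synthesis and transport and 0.080 for glutathione S-transferases, which ended these 3 calls.

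**Figure D1:**
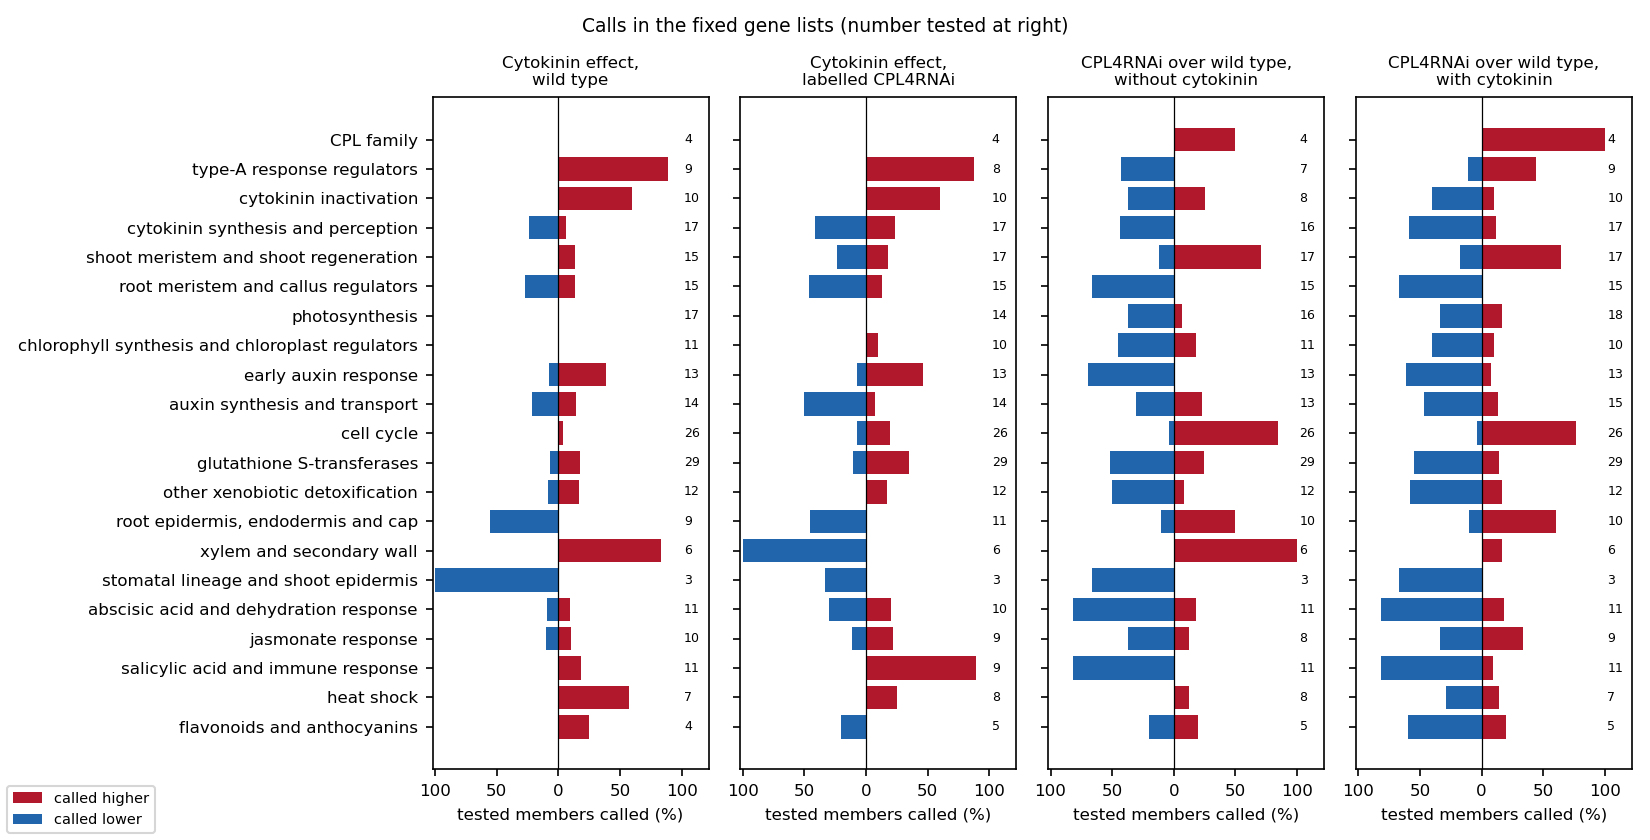
Share of the tested members of each of the 21 fixed gene lists that were called higher (right of 0) or lower (left of 0), in percent, in the 4 comparisons, with the number tested at the right edge of each panel. Type-A response regulators rose with cytokinin in 8 of 9 and 7 of 8 tested members, and the 6 xylem genes include 5 called higher in wild type and 6 called lower in the groups labelled CPL4RNAi.

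The responses of both genotypes to cytokinin, which share no library, overlapped in part and differed for a defined set of genes. Among 18446 genes tested in each, 577 were called higher in both, where independent lists would share 100.4, and 433 were called lower in both, where they would share 59.7. The odds ratios were 15.5 and 24.8. A further 101 genes were called higher in wild type and lower in the groups labelled CPL4RNAi, close to the 107.3 of independent lists, and 2 went the other way, where independent lists would share 55.8. Across 17123 genes with an FPKM of 1 or more in every group, the folds had a Pearson r of 0.50 and a Spearman rho of 0.29. Genes are not independent replicates, so this describes the data only.

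The difference of the cytokinin effect between genotypes, taken as the log2 change in the groups labelled CPL4RNAi minus that in wild type, was called for 460 of 18514 genes at an adjusted p at or under 0.05. It was negative in 373 and positive in 87. Of the 6 xylem and secondary wall genes 4 were called negative (adjusted exact p = 9.9e-05), and the list had a median difference of -3.33. XCP2 went from 1.82 to 13.5 FPKM with cytokinin in wild type and from 23.4 to 15.8 in the groups labelled CPL4RNAi, a difference of -3.45 (SE at most 0.73). XCP1 (AT4G35350) behaved alike, from 2.57 to 17.1 and from 32.3 to 21.0 FPKM, with a difference of -3.36 (SE at most 0.69). CTL2, a chitinase-like gene of secondary walls, and LAC11, a laccase of lignin synthesis, differed by -3.40 (SE at most 0.71) and -3.39 (SE 0.90), and AT5G51890 by -3.22. The lowest of the 4 groups for each of these 5 genes was wild type without cytokinin. Type-A response regulators had 2 of 8 members with a positive difference (adjusted exact p = 0.013), namely ARR7 at 1.07 (SE at most 0.23) and ARR4 at 0.57 (SE 0.16). Early auxin response genes had 2 of 13 with a positive difference (adjusted exact p = 0.023), IAA5 and GH3.6. VND7 and CESA4 differed by -1.88 and -3.57, which was not called, and of the salicylic acid and immune response genes, which rose with cytokinin in the groups labelled CPL4RNAi, 1 of 11 was called positive. Among genes with an FPKM of 5 or more in a group, the 5 largest positive differences were AT3G27950 at 3.53, AT2G16005 at 1.89, IAA5 at 1.76, AT5G47600 at 1.75 and AT3G28600 at 1.66. When only genes with a solved standard error were tested, 151 were called instead of 460. Of the 460, 229 had only an upper bound. The other 231 kept their p-values, so the further loss came from the adjustment over the genes left.

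**Figure D2:**
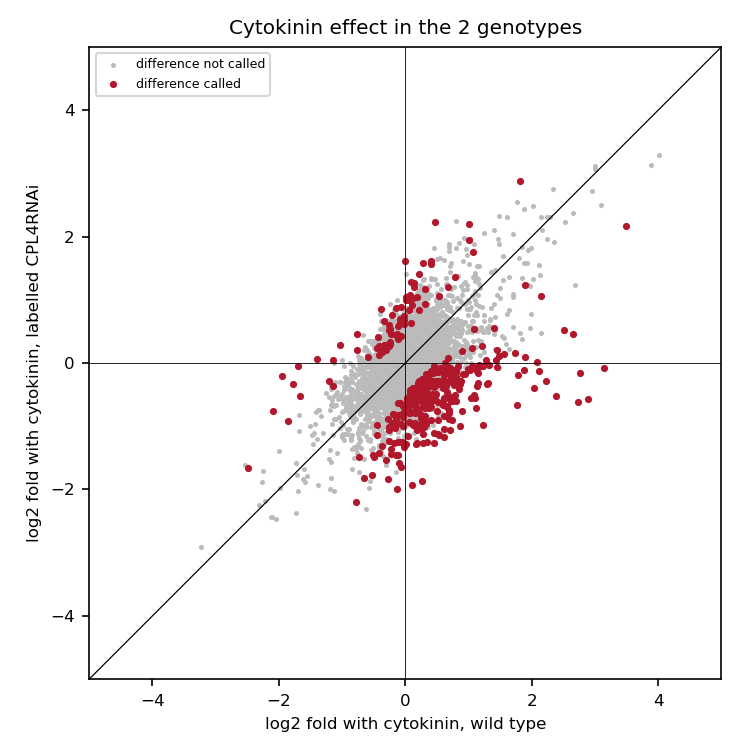
Log2 fold with cytokinin in wild type (horizontal axis) against the groups labelled CPL4RNAi (vertical axis) for 17123 genes with an FPKM of 1 or more in every group, with equal folds on the diagonal line. The 404 red points are genes with a called difference, most of them below the diagonal.

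Without cytokinin, the groups labelled CPL4RNAi had higher levels of shoot meristem, cell cycle and xylem genes than wild type, and lower levels of root meristem and callus regulators and of early auxin response, abscisic acid, salicylic acid and glutathione S-transferase genes. In the shoot meristem and shoot regeneration list 12 of 17 tested genes were higher and 2 lower (12 and 2 adjusted over the list alone; adjusted exact p = 4.9e-04 for higher). WUS (AT2G17950; chromosome 2, 7808871 to 7810795), which sets up the shoot stem cell niche, was listed at 0 in wild type and at 1.32 FPKM in the labelled group, and was called. STM (AT1G62360; chromosome 1, 23058582 to 23061722), which maintains the shoot meristem, went from 0.0652 to 21.7 FPKM (8.38, SE 2.78; q = 0.0094 in the authors' deposited table). The boundary genes CUC1 (AT3G15170) and CUC2 (AT5G53950) were higher by 3.24 (SE at most 0.80) and 1.42 (SE at most 0.35). The meristem gene KNAT1 went the other way, from 20.6 to 6.61 FPKM. ESR1 differed by 0.95 (SE 0.49), which was not called, and CLV3 and ESR2 were not tested. Of 26 cell cycle genes 22 were higher and 1 lower (23 and 1 adjusted over the list alone; adjusted exact p = 5.3e-09 for higher). CYCD3;1, a cyclin gene that cytokinin is known to induce, went from 76.1 to 230.2 FPKM, by 1.60 (SE at most 0.39), and CYCB1;1 was higher by 1.28. All 6 xylem and secondary wall genes were higher (6 adjusted over the list alone; adjusted exact p = 0.0012), with the xylem regulator VND7 at 4.16 (SE at most 1.02) and CESA4 at 3.70 (SE 1.07). Other vascular markers moved apart, the cambium gene PXY from 10.7 to 59.5 FPKM and the phloem genes SUC2 and SEOR1 from 23.7 to 8.52 and from 5.57 to 1.99 FPKM.

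Among the lists lower in the group labelled CPL4RNAi without cytokinin, root meristem and callus regulators had 10 of 15 members lower and 0 higher (10 and 1 adjusted over the list alone; adjusted exact p = 0.0017). WOX5, which marks the root stem cell niche, went from 155.1 to 55.2 FPKM (-1.49, SE at most 0.37), and WOX11 stood at -1.59 (SE at most 0.39). Early auxin response genes had 9 of 13 members lower (10 adjusted over the list alone; adjusted exact p = 0.0023), with IAA5 at -1.69 and GH3.6 at -1.47. Abscisic acid and dehydration response genes had 9 of 11 members lower and 2 higher (9 and 2 adjusted over the list alone; adjusted exact p = 4.9e-04 for lower). RD29A, a gene induced by drought and cold, went from 5.54 to 0.490 FPKM, and HAI2, a phosphatase of the same pathway, stood at -2.90. Salicylic acid and immune response genes had 9 of 11 members lower (10 adjusted over the list alone; adjusted exact p = 4.9e-04). The pathogenesis-related genes PR2 and PR5 stood at -5.62 (SE 1.45) and -4.40 (SE at most 1.08). Glutathione S-transferases had 15 of 29 members lower and 7 higher (15 and 7 adjusted over the list alone; adjusted exact p = 0.0024 for lower), and GSTF2 went from 797.3 to 168.9 FPKM (-2.24).

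Type-A response regulators had 3 of 7 tested members lower and 0 higher in the group labelled CPL4RNAi without cytokinin (4 lower adjusted over the list alone), which did not pass the enrichment test (adjusted exact p = 0.45). ARR9, ARR7 and ARR8 stood at -0.68, -0.59 and -0.38. Cytokinin inactivation genes went both ways, with UGT85A1 at 1.37 and CKX6 at -2.54, and the cytokinin-activating gene LOG5 stood at -3.44. Root epidermis, endodermis and cap genes had 5 of 10 members higher and 1 lower (6 and 1 adjusted over the list alone), which did not pass (adjusted exact p = 0.18 for higher), with MYB36, a regulator of the endodermis, at 3.22 and CASP2 at 1.64. Among called genes with an FPKM of 5 or more in the higher group and above 0 in the lower, the largest rises after STM were MLP28, of the major latex protein family, from 1.46 to 224.1 FPKM (7.26, SE at most 1.79), AT1G63210 at 6.75 and AT1G23160 at 6.46. The largest falls of that set were AT1G76470 at -5.64, PR2, the galactinol synthase gene GolS2 at -4.61 and the late embryogenesis gene LEA4-5 at -4.46. In total 19277 genes were tested and 8492 were called, 4342 higher and 4150 lower, with 2272 changed at least 2-fold. Large folds from a group near 0 were often not called. Among genes at least 16-fold apart with an FPKM of 5 or more in the higher group, 1 of 11 was called where the lower group stood above 0 and at or under 0.1 FPKM, against 21 of 24 where it stood over 0.3.

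With cytokinin present, shoot meristem and cell cycle genes were again higher in the groups labelled CPL4RNAi than in wild type, and root meristem, early auxin response, abscisic acid and salicylic acid genes lower. Shoot meristem and shoot regeneration genes had 11 of 17 members higher and 3 lower (11 and 3 adjusted over the list alone; adjusted exact p = 0.0035 for higher). WUS was listed at 0 in wild type and at 1.28 FPKM in the labelled group, and CUC1, CUC2 and ESR1 were higher by 3.75 (SE at most 0.92), 1.44 (SE at most 0.36) and 1.71 (SE at most 0.42). STM went from 0.0435 to 21.9 FPKM, a difference of 8.97 with an SE of 7.86 that was not called (q = 0.42 in the authors' deposited table). Large folds from near 0 were again seldom called. By the limits used without cytokinin, 2 of 13 were called where the lower group stood above 0 and at or under 0.1 FPKM. Where it stood over 0.3, 24 of 26 were called. The missing call of STM is therefore no evidence of equal levels. Of 26 cell cycle genes 20 were higher and 1 lower (20 and 1 adjusted over the list alone; adjusted exact p = 1.3e-06 for higher), with CYCD3;1 at 1.62 and CYCB1;1 at 1.38. Of the 6 xylem and secondary wall genes 1 was called, VND7 at 2.28 (1 adjusted over the list alone).

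Root meristem and callus regulators had 10 of 15 members lower and 0 higher in the group labelled CPL4RNAi with cytokinin (10 adjusted over the list alone; adjusted exact p = 0.0042), with LBD29 at -2.33 (SE 0.60) and WOX5 at -1.71 (SE at most 0.42). Abscisic acid and dehydration response genes had 9 of 11 members lower and 2 higher (9 and 2 adjusted over the list alone; adjusted exact p = 0.0011 for lower), with RD29A at -3.88 and HAI2 at -2.91. Salicylic acid and immune response genes had 9 of 11 members lower and 1 higher (9 and 1 adjusted over the list alone; adjusted exact p = 0.0011 for lower), with PR5 at -4.14 and PR2 at -4.00. Early auxin response genes had 8 of 13 members lower and 1 higher (8 and 1 adjusted over the list alone; adjusted exact p = 0.025 for lower), with GH3.1 at -1.28 and IAA14 at -1.10. Glutathione S-transferases had 16 of 29 members lower and 4 higher (16 and 5 adjusted over the list alone; adjusted exact p = 0.0042 for lower), with GSTF2 at -2.11 and GSTU25 at 1.85. Cytokinin synthesis and perception genes had 10 of 17 members lower and 2 higher (10 and 2 adjusted over the list alone; adjusted exact p = 0.014 for lower), with LOG5 at -2.96 and LOG1 at -2.73. At a q of 0.01 this last adjusted p became 0.38 and that of the CPL family went from 0.018 to 0.44, which ended both calls.

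Type-A response regulators had 4 of 9 tested members higher and 1 lower with cytokinin (4 and 1 adjusted over the list alone; adjusted exact p = 0.53 for higher). ARR6, ARR7, ARR4 and ARR3 were higher by 0.58, 0.48, 0.45 and 0.43, and ARR9 stood at -0.40 (SE 0.10). Root epidermis, endodermis and cap genes had 6 of 10 members higher and 1 lower (6 and 1 adjusted over the list alone; adjusted exact p = 0.078 for higher), with MYB36 at 2.94 and the root cap gene SMB at 1.94. By the same limits, the largest called rises were AT1G63210 at 7.39 and AGO9, an Argonaute gene, from 0.104 to 13.3 FPKM (SE of the log2 fold at most 1.73), followed by MLP28 at 6.44. The largest falls were AT5G10760 at -5.03, AT5G66780 at -4.99 and AT1G22160 at -4.94, and the germin-like gene GER2 stood at -4.54. Lists that passed the test in none of the 4 comparisons were photosynthesis, with 3 of 18 members higher and 6 lower here (3 and 8 adjusted over the list alone; LHCA2 at -3.22 and LHCB5 at 1.47), and chlorophyll synthesis and chloroplast regulators, with 1 of 10 higher and 4 lower (1 and 4 adjusted over the list alone). So were other xenobiotic detoxification, with 2 of 12 higher and 7 lower (2 and 7 adjusted over the list alone; CYP81D11 at -3.34), jasmonate response, with 3 of 9 higher and 3 lower (3 and 4 adjusted over the list alone; VSP2 at 1.55), and flavonoids and anthocyanins, with 1 of 5 higher and 3 lower (1 and 3 adjusted over the list alone; FLS1 at -1.39). In total 19209 genes were tested and 9493 called, 4741 higher and 4752 lower, with 2519 changed at least 2-fold.

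**Figure D3:**
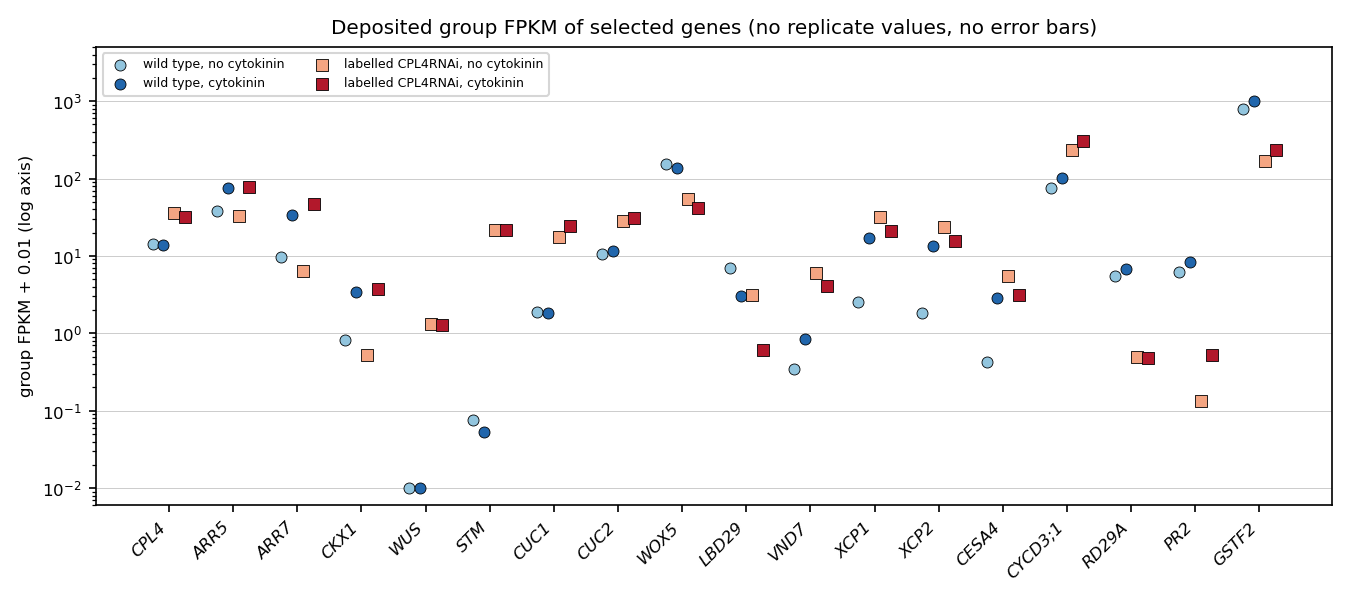
The authors' group FPKM plus 0.01 on a log axis for 18 named genes in the 4 groups (circles, wild type; squares, labelled CPL4RNAi; dark, with cytokinin), without error bars because the table holds no replicate values. STM stands at or under 0.0652 FPKM in wild type and at 21.7 and 21.9 in the labelled groups, and XCP1 and XCP2 are lowest in wild type without cytokinin.

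The differences between genotypes, which share no library across the media, were largely shared. Among 18949 genes tested in both media, 3363 were called higher in both, where independent lists would share 1056.7, and 3448 were called lower in both, where they would share 1028.5. Directions were opposite in 39 and 8 genes. The folds had a Pearson r of 0.88 across 17123 genes, which are not independent replicates. The genotype difference without cytokinin and the cytokinin effect in wild type have the wild-type group without cytokinin in common. Their folds had a covariance of 0.0383 and an r of 0.21. From the shared group alone, 100 simulated sets of unchanged groups gave a mean covariance of 0.0170. The simulated mean r of 0.50 follows from giving the 4 groups equal variance, so it is no measure for the observed r. The covariance exceeded the simulated value by 0.0213. For the cytokinin effect in the groups labelled CPL4RNAi it was -0.0014, against a simulated -0.0171. Among 18702 genes tested in both, 661 were higher with the CPL4RNAi label and with cytokinin in wild type, where independent lists would share 262.1. The shared group by itself raises such a number, and its part in it was not measured. In the pair with the cytokinin effect in the groups labelled CPL4RNAi, the shared group lowers it. There 599 were higher in both, against 356.6 for independent lists, and 535 were higher with the label and lower with cytokinin, against 389.3. The genotype difference averaged over the media and the cytokinin effect averaged over the genotypes had a covariance of 0.0257, against a simulated -1.1e-05.

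Small nuclear RNA genes are transcribed by RNA polymerase II, and read-through past their ends has been described in plants with lowered CPL4. Of 14 tested protein-coding genes starting within 2000 bases downstream of such a gene on the same strand, 5 were called higher and 2 lower without cytokinin (Fisher's exact test for higher, p = 0.33) and 6 higher and 3 lower with it (p = 0.12). Within 5000 bases 12 of 26 were higher without cytokinin (exact p = 0.0078) and 14 of 26 with it (exact p = 0.0020), so that the call depended on the distance. With cytokinin in the groups labelled CPL4RNAi the same kind of genes were also called higher, 4 of 14 within 2000 bases (exact p = 0.025) and 6 of 26 within 5000 (exact p = 0.019), so an excess was seen within a genotype too. It was not seen in wild type, where 0 of 14 and 1 of 25 were called higher with cytokinin. These p-values are not adjusted for the 3 distances. The largest change was in AT1G61280 (chromosome 1, 22603586 to 22604081), which starts 291 bases downstream of the U12 RNA gene. It went from 4.94 to 123.7 FPKM without cytokinin (4.65, SE at most 1.15) and from 5.02 to 160.7 with it (5.00, SE at most 1.23). AT1G16825, 280 bases downstream of a U2 RNA gene, was higher by 1.49 and 1.51. Both genes were picked after their values were seen.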

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

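The tests of the scale of the wild-type group without cytokinin and of phloem markers alone were chosen only after the results were seen, and the test of 8 vascular markers together was written before its values were seen. The cytokinin effect differed between genotypes, by a test of the difference itself, in 460 genes, 87 with a positive and 373 with a negative difference. The positive differences included AT3G27950 (3.53), AT2G16005 (1.89), IAA5 (1.76), AT5G47600 (1.75) and AT3G28600 (1.66). The negative differences included XCP2 (-3.45), CTL2 (-3.40), LAC11 (-3.39), XCP1 (-3.36) and AT5G51890 (-3.22). By list, 2 type-A response regulators and 2 early auxin response genes had a positive difference, and 4 xylem and secondary wall genes a negative difference.

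Xylem genes rose with cytokinin in wild type and fell with it in the groups labelled CPL4RNAi. An even shift of all genes left in the deposited values of the wild-type group without cytokinin is argued against, since the median log2 fold of all tested genes in wild type was 0.0194. This median lay between 0.0030 and 0.0194 in all 4 comparisons, also where 8492 genes were called. It therefore speaks to nothing beyond such an even shift. Less vascular tissue of every kind in that group is argued against by the phloem markers SUC2, APL and SEOR1, whose log2 folds with cytokinin in wild type had upper 95% bounds of at most 0.75, under the xylem median of 2.61. All 8 phloem and cambium markers together had a median difference of -0.59, between the bounds set for and against less vascular tissue, with PXY at -1.51 and ATHB8 at -0.78 called, so that a smaller share of xylem and cambium cells, which could lower xylem genes, and a genotype-dependent response of these genes cannot be told apart. A difference in biology between the genotypes stays open as an untested explanation, as does a single odd library in the wild-type group, for which replicate values would be needed.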

How the results depend on the processing

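The alternatives restricted to solved standard errors and to the smallest standard error or bound over the pairs for every gene were chosen after seeing the data. A reversal of direction was looked for only under the pseudocount and under recentring, and none was found. A pseudocount cannot change the sign of a single gene, so this tests little. Numbers of called genes stayed within 1.5 times their values under adjustment within a comparison, and under an FPKM minimum of 1 or protein-coding nuclear genes alone, each with adjustment within the genes left, so that the filter and the adjustment changed together. Adjustment within a comparison lowered the cytokinin calls from 1938 to 1320 in wild type and from 3313 to 2561 in the labelled groups. It raised the genotype calls from 8492 to 8784 without cytokinin and from 9493 to 9935 with it. Recentring moved folds by at most 0.03 on the log2 scale, too little to test any direction. A q of 0.01 gave 1262 genes for cytokinin in wild type and 2118 in the groups labelled CPL4RNAi, and 222 for the difference between genotypes. A 2-fold minimum gave 518, 669, 2272 and 2519 genes for the cytokinin effects in wild type and in the labelled groups and for the genotype differences without and with cytokinin. The same minimum on log2(FPKM + 1) gave 265, 348, 1613 and 1733. Genes shared between the cytokinin effects numbered 370 higher and 268 lower at a q of 0.01, and 120 and 95 at 2-fold. Those shared between the genotype differences at 2-fold numbered 766 and 835. These settings are stricter by construction. With only solved standard errors the difference was called for 151 genes. There 229 of the 460 calls were left out by construction. The other 231 kept their p-values, so the further loss came from the adjustment over the genes left. The difference was called for 461 genes without the consistency filter. Taking for every gene the smallest standard error or bound over its pairs gave 474 calls. For solved genes this is at most the standard error used otherwise, so that setting is not stricter. The test of genes downstream of small nuclear RNA genes gave exact p = 0.0078 and 0.0020 without and with cytokinin at 5000 bases, and 0.49 and 0.18 at 1000 bases; the cause was not tested. At a q of 0.01, 3 list tests passed that had not: cytokinin synthesis and perception without cytokinin (adjusted exact p = 0.049), auxin synthesis and transport in wild type (0.026, and 0.048 with a background of genes with an FPKM of 1 or more) and root epidermis, endodermis and cap with cytokinin (0.031), and the cause was not tested. Among named gene results a q of 0.01 ended 19 calls, adjustment within a comparison 7, and that adjustment with protein-coding nuclear genes alone 7 and with the FPKM minimum 6. No paired analysis was possible because the values are per group and not per replicate. For the same reason leaving out each replicate, other splits of the samples, a replicate block, a pseudocount per replicate and a count test were not run. What depth limits was not measured, since library depth was not known.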

Other observations

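The tests of CPL4 and of shoot tissue were chosen only after the results were seen, and those of upstream neighbours and chromosome windows were written before their values were seen. Calls were spread unevenly over the classes of RNA. Long noncoding RNAs were rarely called higher in any of the 4 comparisons. In the groups labelled CPL4RNAi they had 2 higher and 35 lower of 136 tested without cytokinin (Fisher's exact test for higher, adjusted exact p = 4.5e-11) and 3 higher and 41 lower of 138 with it, and an excess of lower ones did not pass (adjusted exact p = 0.46 and 0.39). For the cytokinin effects 0 of 134 in wild type and 0 of 133 in the labelled groups were called higher (adjusted exact p = 0.0011 and 1.3e-04). Lower calls were also rare there, 0 of 134 and 3 of 133 (adjusted exact p = 0.036 and 0.015). For cytokinin these RNAs were thus seldom called in either direction. Between genotypes, other noncoding RNAs were lower in the labelled group than in wild type in 40 of 112 without cytokinin (adjusted exact p = 0.0029). In the genotype comparison with cytokinin present, 49 of 113 were lower (adjusted exact p = 1.3e-04). Of 9 tested small nuclear RNA genes 7 were higher without cytokinin in the labelled group (adjusted exact p = 0.0036), 3 of 10 were higher and 2 lower with it (adjusted exact p = 0.89 for higher), and 6 of 10 fell with cytokinin within the labelled groups (adjusted exact p = 6.0e-04). Short RNAs are caught unevenly by such libraries. Plastid genes were seldom lower in the labelled group with cytokinin, 1 of 61 (adjusted exact p = 1.3e-05), as were mitochondrial genes, 1 of 54 (adjusted exact p = 1.2e-04). Without cytokinin 6 of 61 and 7 of 53 were lower (adjusted exact p = 0.085 and 0.37), and an excess of higher genes passed the test in neither class and neither medium.

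CPL4 was higher in both groups labelled CPL4RNAi. Reads of the related gene CPL3 given to CPL4 are argued against, since CPL3 lost -5.78 FPKM, that is, it gained, while CPL4 gained 21.8 FPKM without cytokinin. Swapped genotype labels could give this, as the fold of CPL4 was 1.21 in the medium where it was smaller. No sample outside the 4 groups sets the true direction. AT1G61280, downstream of the U12 RNA gene, was higher in the labelled groups (4.94 to 123.7 FPKM without cytokinin). If it marks read-through it runs the way the labels say, as does AT1G16825 (1.49 and 1.51). Both genes were picked after their values were seen. Within 5000 bases of small nuclear RNA genes, 12 of 26 were higher without cytokinin and 14 of 26 with it (Fisher's exact test, exact p = 0.0078 and 0.0020). Within 2000 bases, 5 of 14 and 6 of 14 were higher (Fisher's exact test, exact p = 0.33 and 0.12). The call depended on the distance, so a swap stays open. Reads from the RNAi construct itself might also add to CPL4, and the genotype effect differed by only -0.11 on the log2 scale between the media. These explanations cannot be told apart here, because a table by gene has no positions along the transcript, and a true rise of CPL4 stays open as an untested explanation.

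A set of 32 genes stood under 1 FPKM in both wild-type groups and at 5 FPKM or more in both groups labelled CPL4RNAi, STM, AGO9, NUB and GEX1 among them, chosen after their values were seen; 17 were called without cytokinin and 19 with it (STM not), and 12 genes showed the reverse. A stretch of chromosome from another strain is argued against, as the 2 fullest windows of 5000000 bases held 21.9% of the genes, where random sets reached 28.1% at their 95th percentile. Shoot tissue left on the roots is argued against, since the photosynthesis list had a median log2 fold of -0.62 in the medium where it was higher. Transcription running in from the gene upstream stays open. Of the 32 genes 34.4% (95% interval 18.6 to 53.2) had an active neighbour upstream on the same strand within 2000 bases, against 19.2% of other low genes (Fisher's exact test, p = 0.041). The other low genes were not matched on their level in the labelled groups, where an active neighbour is also defined, so this excess cannot decide. The interval spans the bound set for and against such transcription. It and a change in gene regulation by genotype cannot be told apart without read positions.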
